A study of Drosophila melanogaster with 8 samples.

How the data were processed

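Flies carrying asense-Gal4 and UAS-stingerGFP laid eggs for 24 h and larvae grew for 5 more days at 25 degrees, per the labels' protocols. Neuroblasts and neurons were sorted by FACS, about 1 µg of total RNA was enriched for polyadenylated RNA, and the libraries kept the strand by dUTP marking, per the labels' protocols. The tools named in the submitters' processing notes are BWA 0.6.1, TopHat 1.4.1, Cufflinks 1.3.0, HTSeq and DESeq 1.8.3, whose roles and order are not given there. Each of the 8 library files holds a Cufflinks table with 1 FPKM per gene, its confidence interval and a status, per the file headers. FPKM is normalized by the authors to transcript length and to the mapped fragments of the library. The authors' deposited table holds a fold (ratio), its log2, and p-values with their adjustment, per the file headers, and its largest adjusted p is 0.00995. Its direction, neuroblast over neuron, was read from the name of the comparison and is not in the headers. Its 3 columns of mean signal were not used here, since their names do not show the cell type. The genome build is not given in the sources used here. Coordinates are those of the files, written with a 1-based start. A reference annotation of another build, release 115, gave only gene names, biotypes, transcript lengths and overlaps, and 13575 of the 14210 gene identifiers matched it. Whether the counting used the strand is not given in the sources used here, so values of overlapping genes on opposite strands are uncertain.

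The labels mark technical replicates, which were averaged on the log2 scale into 3 neuroblast and 2 neuron biological replicates. Nothing in the labels says whether these come from separate animals or sorts, so p-values measure only the spread between these samples. Group means and SDs of FPKM are over biological replicates, where the FPKM of a replicate is the mean of its libraries. The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) with an intensity trend in the prior variance, two-sided, with Benjamini-Hochberg adjustment over the 7975 genes with at least 1 FPKM in at least 2 biological replicates, at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. A gene under 1 FPKM in all replicates of a cell type entered only through the other, so its direction was close to given by the filter. With 3 against 2 replicates the variance of each gene rests on few values, and limma borrows it across genes.

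The FPKM sums of the libraries ran from 321551 to 753682 and were higher in neuroblasts. Depth was read from the Cufflinks interval, whose upper bound lies 2 SD of a count above the value. The fragments of genes with a single transcript came out whole within 0.05 for 91.3% to 91.9% of values under 200 fragments. They summed to 2278417 in neuroblast 1, 2647037 and 2184305 in the libraries of neuroblast 2, 5903628 and 16282071 in those of neuroblast 3, 1443262 and 1258113 in those of neuron 1 and 953171 in neuron 2. Neuroblast 1, neuroblast 2 and neuron 1 share a flow cell, as the file names give it, and the others do not, so most of the flow cells hold 1 cell type. Cufflinks gave a status other than OK to 85 genes in at least 1 library.

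Before the data were examined, 29 gene lists, the tests, the alternatives and the rule for named genes were fixed. Of these lists, 26 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and 17 were called, 10 toward neuroblasts and 7 toward neurons. With an estimated correlation limma's camera called 0 of the 26, and 0 at an unadjusted p under 0.05. Named are 10 check genes (dpn, ase, mira, wor, CycE, elav, n-syb, brp, pros, repo). Named too are the 10 genes with the largest log2 fold change in each direction among those called, with no overlap of replicates and a mean of at least 10 FPKM in the higher group. From each list the rule takes up to 4 members with the smallest adjusted p and up to 3 called members against the majority. The rule took 157 genes, of which the text prints a part. There was no column of per-sample values that could not be given to a sample (0 columns).

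The script was tested on simulated data with the real genes' means and spreads, for neuroblast against neuron over 7975 genes. Of 50 genes changed 8-fold it recovered 72%, of 50 changed 4-fold 46%, of 50 changed 2-fold 2% and of 50 changed 1.5-fold 0%, with 1 unchanged gene called. No other genes were changed in the simulation, and 61 were called, against 5048 in the real data. The adjustment was therefore stricter in the simulation, and its recoveries do not describe the real comparison. Alternatives covered the pseudocount, the filter, the scaling, the treatment of technical replicates, the prior variance, a replicate block, the threshold, the flow cell and each replicate left out. Added after seeing the data were scaling to the protein-coding sum, genes with status OK in every library, neuroblast 2 and 3 against neuron 1, and limma-voom on the recovered fragments. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.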

Results

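The series measured polyadenylated RNA of 2 cell types sorted from the brain of late-stage Drosophila melanogaster larvae. Neuroblasts are the stem cells of the larval brain, which divide asymmetrically to renew themselves and to give rise to the differentiated daughter cells, the neurons. Both were sorted by flow cytometry from flies in which asense-Gal4 drives the nuclear green fluorescent protein stinger. There were 8 libraries, 5 of neuroblasts and 3 of neurons. They make 3 neuroblast replicates and 2 neuron replicates, since neuroblast 2, neuroblast 3 and neuron 1 were each sequenced as a pair of technical replicates. The files list 14210 genes with a value in FPKM (fragments scaled to transcript length and library size), and 7975 of them reached 1 FPKM in at least 2 biological replicates and were tested. The fragments recovered for genes with a single transcript ranged from 953171 in neuron 2 to 16282071 in the second technical replicate of neuroblast 3.

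Technical replicates differed little. The SD across genes of the log2 difference between 2 libraries was 0.118 to 0.297 for the 3 technical pairs. It was 0.498 to 0.854 for the 8 pairs of libraries from different neuroblast replicates and 0.562 to 0.569 for the 2 pairs from different neuron replicates. Between the cell types it was 1.63 to 2.25 over 15 pairs. Spearman correlations across genes, which are not independent replicates, were 0.988 to 0.999 for technical pairs and 0.460 to 0.648 between cell types. 

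The comparison of neuroblasts with neurons asks which genes distinguish the stem cells from their daughters, and 10 check genes were read first. The neuroblast transcription factor deadpan (dpn, FBgn0010109, chromosome arm 2R, 4116476 to 4119832) stood at 136 ± 16.5 FPKM in neuroblasts (SD, n = 3) and 3.31 ± 1.36 in neurons (SD, n = 2). Miranda (mira, FBgn0021776, 3R, 15757521 to 15760842), the adaptor that carries fate determinants into the daughter cell, stood at 848 ± 124 and 9.45 ± 1.46 FPKM. On the log2(FPKM + 1) scale dpn was higher in neuroblasts by 5.02 (SE 0.29), mira by 6.34 (SE 0.26), the Snail family factor worniu (wor) by 3.68 and the S phase cyclin CycE by 5.28. The pan-neuronal RNA-binding protein gene elav (FBgn0260400, X, 406496 to 417259) stood at 34.2 ± 23.6 FPKM in neuroblasts and 378 ± 81.1 in neurons, a log2 fold change of -3.71 (SE 0.65). The synaptic genes n-syb and brp had log2 fold changes of -3.98 and -4.17. The limma adjusted p-values of these 7 genes lay between 0.000196 for mira and 0.00946 for brp.

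The calls for ase and pros depended on single replicates and on the processing. The proneural gene asense (ase), whose driver marks the sorted cells, stood at 77.7 ± 24.7 FPKM in neuroblasts and 33.7 ± 17.5 in neurons, a log2 fold change of 1.24 with a limma adjusted p of 0.0314. Without neuron replicate 1 it was 0.70, with a limma adjusted p of 0.241, and without neuroblast replicate 1 or 3 it was 1.00 and 1.29, with 0.0623 and 0.0588. The call was also lost with upper quartile scaling at 0.86, with median ratio scaling at 1.07, with quantile normalization at 0.88, with the replicate block at 1.29 and with the protein-coding sum at 0.49, where limma gave an adjusted p of 0.316. The homeodomain gene prospero (pros) stood at 97.7 ± 38.5 and 319 ± 196 FPKM, a log2 fold change of -1.62 with a limma adjusted p of 0.0230. Without neuron replicate 2 it was -0.95, with a limma adjusted p of 0.180, and without neuroblast replicate 2 or 3 it was -1.61 and -1.34, with 0.0516 and 0.0641. On the shared flow cell alone it was -0.67, with a limma adjusted p of 0.189, and with the replicate block -1.34, with 0.0769, and with neuroblast 2 and 3 against neuron 1 -1.24, with 0.108. The glial gene repo was higher in neurons, at 0.597 ± 0.429 FPKM in neuroblasts and 8.81 ± 1.19 in neurons, with a log2 fold change of -2.65 and a limma adjusted p of 0.000847. Neither n-syb nor brp passed without neuron replicate 2, at log2 fold changes of -3.94 and -3.79, and n-syb did not pass without neuron replicate 1 either, at -4.03. On the shared flow cell brp had -2.75.

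**Figure D1:**
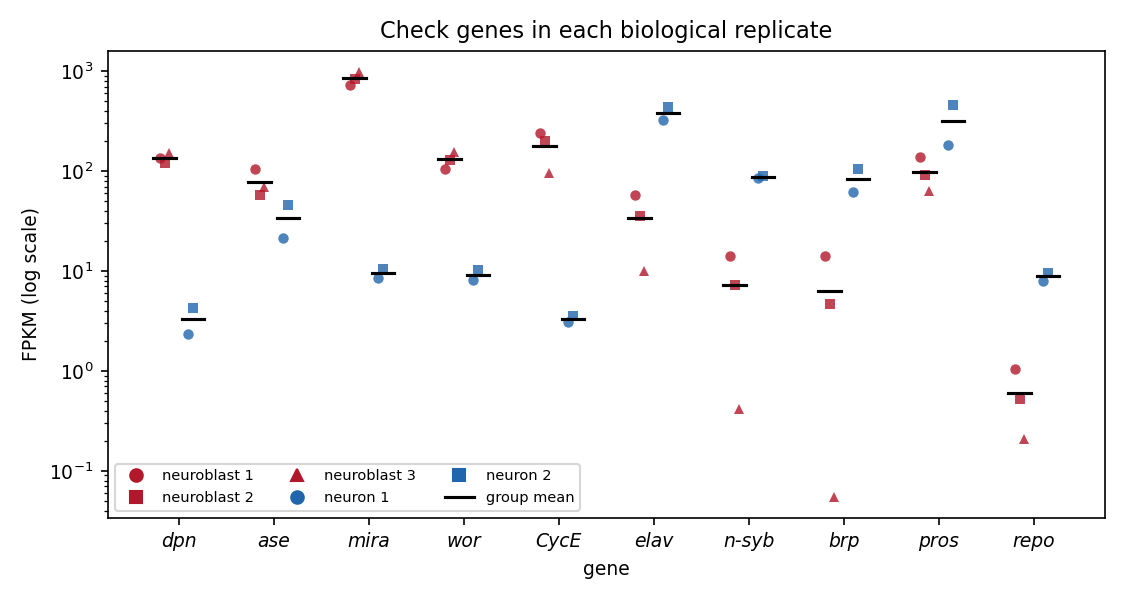
FPKM of the 10 check genes on a log axis, one symbol per biological replicate (3 neuroblast, 2 neuron), with a bar at each group mean. Neuroblast 3 lies below the other neuroblast replicates for the neuronal genes elav, n-syb and brp, and all 3 neuroblast replicates of dpn, mira, wor and CycE lie above both neuron replicates.

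With limma at an adjusted p under 0.05, 2667 genes were higher in neuroblasts and 2381 were higher in neurons. Of the 7975 tested genes, 6267 had no overlap between the replicates of the groups, where chance gives 20% of genes. With a minimum log2 fold change of 1, the counts were 2398 and 2063. Without neuron replicate 2, 1674 genes were called higher in neuroblasts and 1600 higher in neurons. The split depends on the scaling: with the libraries scaled to the same sum of protein-coding FPKM, an alternative chosen after seeing the data, 1744 genes were higher in neuroblasts and 3493 in neurons, so that the share higher in neuroblasts was 33.3% and not 52.8%. The median log2 fold change of all tested genes was 0.17 as deposited, -0.17 with upper quartile scaling, 0.01 with median ratio scaling and -0.53 with the protein-coding sum, and the values of genes and lists stand relative to that shift. None of the called genes was called in the opposite direction with these scalings or with quantile normalization, and 4125 of the 5048 kept their call with the protein-coding sum.

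The genes with the largest log2 fold changes toward neuroblasts included BthD, a selenoprotein gene on X (FBgn0030501, 13506147 to 13507261), with a log2 fold change of 7.13 (SE 0.33). The putative noncoding RNA pncr002:3R stood at 10791 ± 2622 and 87.5 ± 15.6 FPKM. Aldh, an aldehyde dehydrogenase gene, stood at 227 ± 31.7 and 1.22 ± 0.895 FPKM, and the importin gene Pen at 914 ± 218 and 11.2 ± 3.17 FPKM. CG13023, CG6486, which the reference names Pex7, CG16879, CG13305 and CG15646 had log2 fold changes from 5.85 to 6.74. By the rule that named them, these 9 genes and mira were higher in all 3 neuroblast replicates than in both neuron replicates. Their limma adjusted p-values were 0.000196 to 0.000219.

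The replication and division genes were higher in neuroblasts. Of the 35 tested DNA replication genes 34 were higher in neuroblasts and 0 in neurons, over all genes and adjusted over the list alone, with a median log2 fold change of 3.91. Mcm6 and Mcm3, subunits of the replicative helicase, stood at 233 ± 65.2 and 246 ± 47.8 FPKM in neuroblasts against 5.37 ± 0.099 and 7.12 ± 0.298 in neurons. The licensing factor dup stood at 155 ± 28.3 against 3.38 ± 0.608 FPKM. Of 44 cell cycle and mitosis genes 35 were higher in neuroblasts and 0 in neurons, 37 and 0 adjusted over the list alone, with a median of 2.65. CycA stood at 525 ± 138 against 27.8 ± 1.41 FPKM, CycB at 312 ± 84.9 against 17.3 ± 0.607, and Incenp, of the chromosomal passenger complex, at 156 ± 16.3 against 10.3 ± 0.384. With camera at a preset correlation the adjusted p was 2.74e-13 for replication and 3.93e-10 for the cell cycle, and adjusted p = 0.431 for both with an estimated correlation. The DNA replication genes stood in the neuron replicates at a median of 3.68% and 3.90% of their neuroblast level.

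Genes of ribosome production and translation followed the same direction. Of 42 ribosome biogenesis and growth genes 37 were higher in neuroblasts and 0 in neurons, with a median of 2.34. Adjusted over the list alone the counts were 37 and 1. The box C/D particle gene hoip stood at 268 ± 102 FPKM in neuroblasts and 14.4 ± 3.35 in neurons, and RpI1, the largest subunit of RNA polymerase I, at 66.5 ± 18.9 and 5.15 ± 0.204. Of 85 cytosolic ribosomal protein genes 76 were higher in neuroblasts and 1 in neurons, 78 and 1 adjusted over the list alone, with a median of 1.69. With quantile normalization the counts were 9 and 1 and the median 0.56, and with the protein-coding sum 39 and 1 and 0.92. Without neuron replicate 1 the counts were 10 and 1, and without neuron replicate 2 they were 13 and 0. RpS5b was the exception at 2.40 ± 0.415 FPKM in neuroblasts and 6.84 ± 2.55 in neurons, and without neuron replicate 2 its log2 fold change of -0.84 had a limma adjusted p of 0.125. Ribosomal protein genes have near-identical copies, among them RpS15Ab and RpL34a, so values of single members are uncertain. The share of FPKM in cytosolic ribosomal protein genes was 27.1% to 29.7% in neuroblast libraries and 14.8% to 15.3% in neuron libraries. Of 74 mitochondrial ribosomal protein genes 70 were higher in neuroblasts and 0 in neurons, 72 and 0 adjusted over the list alone, with a median of 2.20, and mRpL46 stood at 74.8 ± 22.5 against 4.20 ± 0.660 FPKM. Of 36 aminoacyl tRNA synthetase and translation factor genes 25 were higher in neuroblasts and 0 in neurons, over all genes and adjusted over the list alone, with Aats-val and Aats-ile at log2 fold changes of 2.43 and 2.38. The counts were 20 and 1 with quantile normalization, 16 and 2 with the protein-coding sum and 15 and 0 without neuron replicate 2. The camera adjusted p-values were 1.61e-09, 8.40e-09, 4.70e-13 and 1.06e-05 in the order named. With an estimated correlation the lists had adjusted p = 0.431, except translation with adjusted p = 0.438.

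Energy metabolism and splicing genes were also higher in neuroblasts. Of 34 oxidative phosphorylation genes 33 were higher in neuroblasts and 0 in neurons, over all genes and adjusted over the list alone, with a median of 2.06, and SdhC, a succinate dehydrogenase subunit, stood at 192 ± 44.1 against 26.2 ± 0.993 FPKM. Of 12 glycolysis genes 11 were higher in neuroblasts and 0 in neurons, over all genes and adjusted over the list alone, with a median of 2.04. Pyruvate kinase (PyK) stood at 302 ± 81.5 against 26.0 ± 8.29 FPKM and Gapdh1 at 359 ± 141 against 51.6 ± 6.52. Of 32 spliceosome genes 22 were higher in neuroblasts and 0 in neurons, over all genes and adjusted over the list alone, with a median of 0.96. The counts were 15 and 0 with upper quartile scaling, 14 and 1 with quantile normalization and 11 and 2 with the protein-coding sum, with medians of 0.58, 0.52 and 0.20, and 10 and 0 without neuron replicate 1 and 12 and 0 without neuron replicate 2. SmD1 and SmD2 of the Sm ring stood at 260 ± 52.6 and 416 ± 73.5 against 45.4 ± 3.01 and 68.9 ± 8.46 FPKM. The camera adjusted p-values were 8.40e-09, 0.000319 and 0.000107. With an estimated correlation they were adjusted p = 0.431, adjusted p = 0.431 and adjusted p = 0.498.

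Genes known for neuroblast identity went both ways. Of 23 neuroblast transcription and fate factors 12 were higher in neuroblasts and 10 in neurons, over all genes and adjusted over the list alone, and camera gave an adjusted p of 0.418. Without neuron replicate 2 the counts were 11 and 5. Besides dpn, mira and wor, the factor grainyhead (grh, FBgn0259211, 2R, 13690294 to 13729584) stood at 148 ± 27.7 FPKM in neuroblasts and 1.64 ± 0.347 in neurons, a log2 fold change of 5.82, and the zinc finger gene klu had a log2 fold change of 3.91. Higher in neurons were mamo, the Snail family gene esg and hbn, with log2 fold changes of -4.48, -4.11 and -3.50. The call for mamo was lost without neuron replicate 1 or 2, with limma adjusted p-values of 0.0550 and 0.0847 at log2 fold changes of -4.82 and -4.14. Of 27 asymmetric division genes 15 were higher in neuroblasts and 4 in neurons, 17 and 4 adjusted over the list alone, with a median of 1.34. The counts were 14 and 7 with quantile normalization and 10 and 8 with the protein-coding sum, with medians of 0.92 and 0.58, and 13 and 2 without neuron replicate 2 and 14 and 2 without neuroblast replicate 2. Inscuteable (insc), which orients the spindle, had a log2 fold change of 3.90 and staufen (stau), an RNA-binding partner of Miranda, stood at 390 ± 54.8 against 55.4 ± 0.530. The growth regulator brat and the kinesin gene Khc-73 were higher in neurons, at -1.87 and -2.61. The camera adjusted p of this list was 0.0103, with adjusted p = 0.431 with an estimated correlation and adjusted p = 0.0811 with quantile normalization.

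Of 15 temporal patterning factors 3 were higher in neuroblasts and 7 in neurons, over all genes and adjusted over the list alone, with a camera adjusted p of 0.121, and 0.0446 with a filter at 5 FPKM. The counts were 3 and 2 without neuron replicate 2. Toward neuroblasts were grh, tll and CG17838, which the reference names Syp and which stood at 2432 ± 1292 FPKM in neuroblasts and 207 ± 43.3 in neurons. Among those toward neurons was eyeless (ey), at 11.8 ± 1.88 against 66.6 ± 5.31 FPKM. Of 9 markers of type II lineages, the neuroblast lineages that make intermediate progenitors, 1 (tll) was higher in neuroblasts and 7 in neurons, 2 and 7 adjusted over the list alone. Among them erm, which is active in intermediate progenitors, stood at 6.36 ± 3.92 against 78.0 ± 8.83 FPKM. The camera adjusted p of 0.0299 was lost with adjusted p = 0.438 with an estimated correlation, and it was 0.0551 with a filter at 5 FPKM, 0.0695 with upper quartile scaling, 0.0529 with median ratio scaling, 0.0626 on the shared flow cell and 0.107 with the protein-coding sum. The cells were sorted with asense-Gal4, and how far this driver marks type II neuroblasts was not measured here. The counts of the type II list thus do not describe type II neuroblasts. Of 30 Notch pathway genes 7 were higher in neuroblasts and 9 in neurons, over all genes and adjusted over the list alone, with a camera adjusted p of 0.180. The counts were 6 and 16 with upper quartile scaling, 2 and 19 with the protein-coding sum and 5 and 5 without neuron replicate 1. The Enhancer of split genes parted: HLHmgamma had a log2 fold change of 3.76, while HLHm7 stood at 8.89 ± 2.21 FPKM in neuroblasts and 69.7 ± 4.84 in neurons and m6 at 2.60 ± 2.15 and 64.6 ± 6.16. The Notch ligand Dl and the Notch trafficking gene spdo were higher in neuroblasts, by 1.68 and 1.90. With the protein-coding sum Dl did not pass, at 0.98 with a limma adjusted p of 0.0832, and spdo stood at 1.16. With neuroblast 2 and 3 against neuron 1 Dl had 1.75 and 0.0568.

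**Figure D2:**
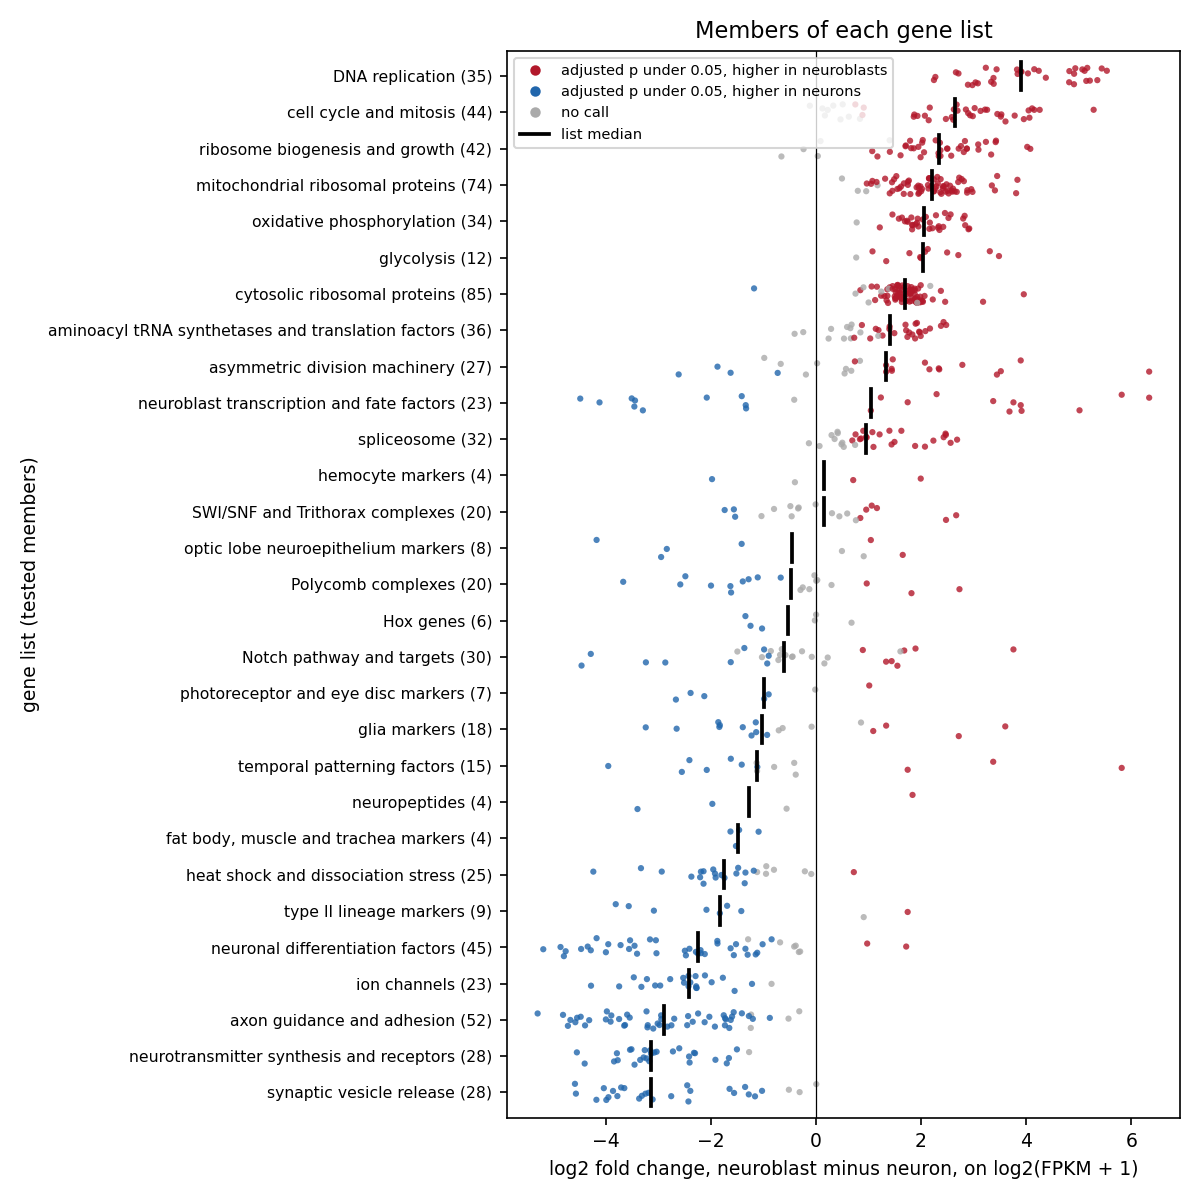
Log2 fold change of each tested member of the 29 gene lists, neuroblast minus neuron on the log2(FPKM + 1) scale, with 1 point per gene coloured by its limma call and a bar at the list median. DNA replication has the highest median, 3.91, and synaptic vesicle release and neurotransmitter genes the lowest, -3.14. Medians near 0, such as 0.15 for SWI/SNF and Trithorax genes, change sign with upper quartile scaling.

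Most members of the 5 lists fixed for neuronal genes were higher in neurons. Of 28 synaptic vesicle release genes 25 were higher in neurons and 0 in neuroblasts, over all genes and adjusted over the list alone, with a median of -3.14. Of these, 11 were called without neuron replicate 2. Stoned B (stnB), of vesicle recycling, stood at 9.45 ± 1.02 FPKM in neuroblasts and 69.0 ± 2.36 in neurons. Of 28 neurotransmitter genes 27 were higher in neurons and 0 in neuroblasts, 28 and 0 adjusted over the list alone, with a median of -3.14. The GABA-synthesizing enzyme gene Gad1 stood at 0.883 ± 0.694 against 15.7 ± 0.727 FPKM and acetylcholinesterase (Ace) at 0.650 ± 0.430 against 8.75 ± 0.778. Of 23 ion channel genes 22 were higher in neurons and 0 in neuroblasts, 23 and 0 adjusted over the list alone, with a median of -2.42. Of 52 axon guidance and adhesion genes 48 were higher in neurons and 0 in neuroblasts, over all genes and adjusted over the list alone, with a median of -2.88, among them the guidance cue NetA at 0.298 ± 0.254 against 10.8 ± 0.966 FPKM. Of 45 neuronal differentiation factors 37 were higher in neurons and 2 in neuroblasts, over all genes and adjusted over the list alone, with a median of -2.24. Without neuron replicate 1 the counts were 29 and 0, and without neuron replicate 2 they were 24 and 1. The POU domain gene acj6 stood at 0.192 ± 0.137 against 4.62 ± 0.268 FPKM. Against this direction were fru and apt, at 1.72 and 0.98. Both calls were lost without neuron replicate 1, where fru had 1.55 and a limma adjusted p of 0.0850 and apt 0.70 and 0.165. Without neuron replicate 2 fru had 1.89 and 0.0543, and without neuroblast replicate 1 apt had 0.84 and 0.0688. With the protein-coding sum fru had 1.03 and a limma adjusted p of 0.117 and apt 0.22 and 0.557, and apt did not pass with upper quartile scaling (0.60), quantile normalization (0.55) or the replicate block (1.07) either. The camera adjusted p-values of the 5 lists were 2.94e-07, 1.61e-09, 2.01e-08, 4.70e-13 and 8.43e-09, and adjusted p = 0.431 for each with an estimated correlation.

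The neuroblast replicates differed in these neuronal genes. Among the members with at least 5 FPKM in neurons, the 28 synaptic vesicle genes stood at a median of 18.1% of the neuron level in neuroblast 1, 8.53% in neuroblast 2 and 2.28% in neuroblast 3. For 23 neurotransmitter genes the medians were 14.3%, 7.22% and 0.392%, and for 19 ion channel genes 17.2%, 7.90% and 0.385%. For 50 axon guidance genes they were 18.8%, 13.6% and 6.45%, and for 39 differentiation factors 20.5%, 12.6% and 7.21%.

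**Figure D3:**
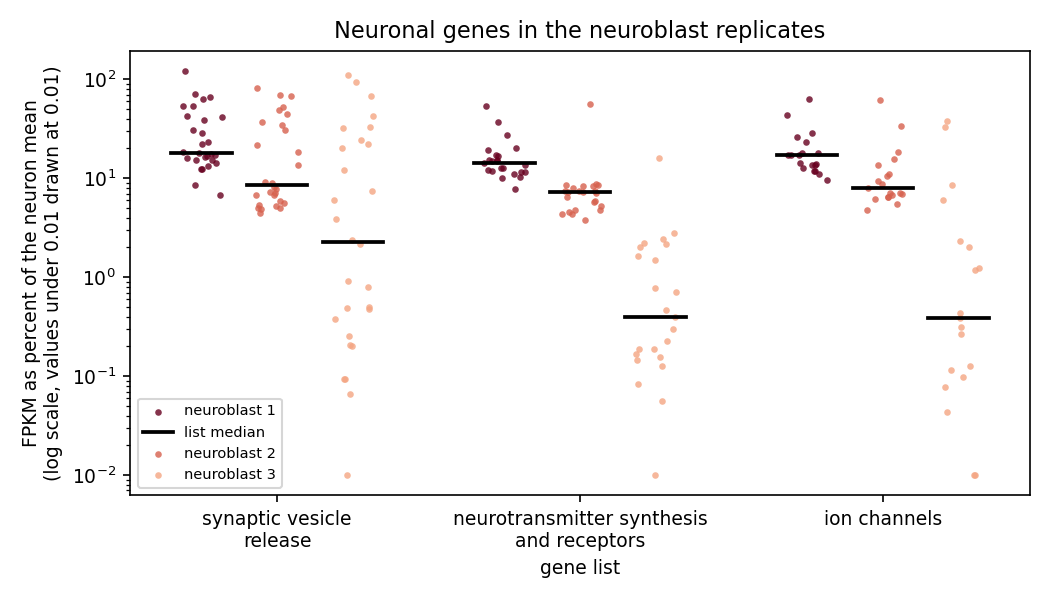
FPKM of neuronal genes in each neuroblast replicate as a percent of the neuron mean, on a log axis, for members of 3 lists with at least 5 FPKM in neurons (28, 23 and 19 genes). Points are genes and bars are list medians, which run from 18.1% for synaptic vesicle genes in neuroblast 1 to 0.385% for ion channel genes in neuroblast 3.

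The genes with the largest log2 fold changes toward neurons included the zinc finger gene nerfin-1 (FBgn0028999, 3L, 909139 to 912319), at 46.1 ± 46.4 FPKM in neuroblasts and 923 ± 166 in neurons, a log2 fold change of -5.18 (SE 1.18). The adhesion gene Dscam2 (FBgn0263218, 3L, 7152415 to 7183017) stood at 12.2 ± 12.6 and 278 ± 5.50 FPKM, a log2 fold change of -5.29. Ank2, an ankyrin, and the RNA-binding protein gene Rbp6 had -5.15 and -5.10, CG34377 and CG9650 had -4.94 and -4.93, and the dosage compensation RNA roX2 had -5.11. Without neuron replicate 2 nerfin-1, Dscam2, Ank2 and Rbp6 no longer passed, with limma adjusted p-values of 0.0627, 0.0564, 0.0511 and 0.119, while their log2 fold changes stayed about as large, for nerfin-1 at 0.964 of the value with all replicates and for the others at -5.27, -5.17 and -4.82. On the shared flow cell Rbp6 had -3.18, and with a pseudocount of 0.1 it did not pass, with a limma adjusted p of 0.0529. Without neuron replicate 1 Dscam2, Rbp6 and RNaseP:RNA did not pass, with limma adjusted p-values of 0.0528, 0.0900 and 0.0684 at log2 fold changes of -5.31, -5.38 and -4.67. The structural RNAs snRNA:7SK, RNaseP:RNA and RNaseMRP:RNA, which lack a poly(A) tail, also belonged to this group, at -6.34, -5.66 and -5.18. Their neuron replicates were far apart, at 8716 and 908 FPKM for snRNA:7SK and 1719 and 101 FPKM for RNaseMRP:RNA, and without neuron replicate 1 RNaseMRP:RNA had a log2 fold change of -3.15.

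Chromatin regulators moved in both directions, as did the tested genes at large, of which 2667 of 7975 were higher in neuroblasts and 2381 in neurons. Of 20 SWI/SNF and Trithorax genes 6 were higher in neuroblasts and 3 in neurons, 5 and 3 adjusted over the list alone, with a camera adjusted p of 0.791. The balance turned with the scaling, to 4 and 7 with upper quartile scaling, 4 and 9 with quantile normalization and 2 and 9 with the protein-coding sum. It was 2 and 1 without neuron replicate 1 and 3 and 0 without neuron replicate 2. Nurf-38 and ash2 were higher in neuroblasts, at 370 ± 128 against 55.4 ± 6.29 and 138 ± 36.4 against 23.7 ± 5.66 FPKM. The SWI/SNF subunit osa stood at 45.7 ± 17.9 against 131 ± 28.6 FPKM, and without neuron replicate 2 its log2 fold change of -1.34 had a limma adjusted p of 0.0932. Of 20 Polycomb genes 3 were higher in neuroblasts and 10 in neurons, over all genes and adjusted over the list alone, with a camera adjusted p of 0.0662. Without neuron replicate 1 the counts were 2 and 6. The list was called with a pseudocount of 0.1 (0.0466), with a filter at 5 FPKM (0.0186) and with quantile normalization (0.0162). The PRC2 subunit esc stood at 34.6 ± 5.05 against 4.32 ± 0.371 FPKM, whereas the PRC1 subunit ph-p stood at 16.7 ± 5.48 against 101 ± 13.4 and Su(z)2 at 2.00 ± 1.64 against 33.0 ± 6.42.

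Markers of other cells in and around the larval brain went both ways. Of 18 glia markers 4 were higher in neuroblasts and 10 in neurons, 5 and 11 adjusted over the list alone, with a camera adjusted p of 0.0662. The counts were 4 and 6 with quantile normalization, 2 and 12 with the protein-coding sum and 2 and 8 without neuron replicate 2. The transporter genes Eaat1 and Tret1-1 were higher in neuroblasts, at 65.1 ± 5.09 against 9.05 ± 0.244 and 24.5 ± 7.05 against 1.04 ± 0.177 FPKM. Of 14 hemocyte markers found 4 passed the filter, with 2 higher in neuroblasts and 1 in neurons. Of 20 fat body, muscle and trachea markers found 4 passed it, and all 4 were higher in neurons. The counts adjusted over each list alone were the same. Mlc1, bt, trh and the hemocyte marker Pxn stayed under 1 FPKM in all neuroblast replicates, and nimC4 in both neuron replicates. The filter thus passed them only through the cell type called higher. Mlc1, bt and trh were low there too, with neuron means of 2.24, 2.88 and 2.27 FPKM. The hemocyte counts were 1 and 1 with upper quartile scaling and 1 and 2 with the protein-coding sum. The call for nimC4, at 0.71 with a limma adjusted p of 0.0471, was lost in most alternatives, among them without neuroblast replicate 2 (0.78) or 3 (0.53) and without neuron replicate 1 (0.76) or 2 (0.67), and crq was lost without neuron replicate 1 (1.88, 0.0790) or 2 (2.11, 0.0618). The hemocyte gene Pxn stood at 0.385 ± 0.262 against 4.40 ± 0.708 FPKM. Of 19 photoreceptor and eye disc markers found 7 passed the filter, with 1 higher in neuroblasts and 5 in neurons, over all genes and adjusted over the list alone. The camera adjusted p was 0.0569, and 0.0488 without neuroblast replicate 2. With quantile normalization the counts were 1 and 3, and with the protein-coding sum 0 and 5. Among these markers eys stood at 0.497 ± 0.441 against 8.18 ± 0.263 FPKM. Of 8 optic lobe neuroepithelium markers 2 were higher in neuroblasts and 4 in neurons, 3 and 4 adjusted over the list alone, with a camera adjusted p of 0.539. They were 1 and 4 with the protein-coding sum and 3 and 4 with quantile normalization. Of 28 neuropeptide genes found 4 passed the filter, with 1 higher in neuroblasts and 2 in neurons. Of 9 genes of the Hox list 6 passed it, with 0 and 3. The counts adjusted over each list alone were the same. The 3 called members of the Hox list were the Hox genes Ubx and abd-A and the Hox cofactor gene exd. Without neuron replicate 2 exd, Ubx and abd-A stood at -1.01, -0.91 and -0.77 and lost their calls. On the shared flow cell they lost them too, and with quantile normalization the counts were 1 and 1. The camera adjusted p of the Hox list was 0.343, and the lists with 4 genes past the filter were too small for camera.

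Heat shock and dissociation stress genes were higher in neurons. Of 25 genes 1 was higher in neuroblasts and 18 in neurons, over all genes and adjusted over the list alone, with a median of -1.74. The JNK phosphatase gene puc stood at 7.75 ± 3.45 FPKM in neuroblasts and 61.8 ± 9.44 in neurons. The inducible chaperone gene Hsp70Ba stood at 25.6 ± 4.25 against 97.9 ± 9.71 FPKM, although the Hsp70 copies are near-identical and their single values uncertain. Toward neuroblasts was Hsc70Cb at 0.72, with a limma adjusted p of 0.0432, which did not pass without neuroblast replicate 1 (0.77), neuroblast replicate 2 (0.77), neuron replicate 1 (0.88) or neuron replicate 2 (0.56), and which was -0.04 with the protein-coding sum. The camera adjusted p of the list was 1.74e-05, and adjusted p = 0.431 with an estimated correlation.

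The authors' deposited table lists 3532 genes, 1702 higher in neuroblasts and 1830 higher in neurons, each with an adjusted p under 0.01. It was made from the same libraries and is no independent evidence. Of these genes 3261 (92.3%) were called in the same direction here with limma, 0 in the opposite direction, and 74 were tested without a call. The other 197 were not past the filter on low values. The Spearman correlation across 3306 genes of the log2 fold changes was 0.934. For mira the authors' deposited table gives a log2 fold change of 6.20, for dpn 5.13, for BthD 8.31, for elav -3.70 and for nerfin-1 -4.55. Of the genes called here 1787 are not in the authors' deposited table.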

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

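Tests added after seeing the data were the scaling to the protein-coding sum, the genes with status OK in every library, neuroblast 2 and 3 against neuron 1, and limma-voom on recovered fragments. The other alternatives were planned. The number of genes higher in neuroblasts (2667) left the range of 1.5 times without neuron replicate 2 (1674), with neuroblast 2 and 3 against neuron 1 (1622) and scaled to the sum of protein-coding FPKM (1744), where the rescaling itself lowers every neuroblast value, and without each replicate in turn it ran from 1674 to 2629. The number higher in neurons (2381) stayed within 1.5 times in all 23 alternatives and ran from 1600 to 2432 without each replicate in turn. The neuron left alone is assumed to vary like the neuroblasts. The labels share only a number between the cell types, and with 2 pairs the replicate block gave 2047 and 1977 genes. The deviations of same-numbered samples correlated at -0.52 and -0.39 across genes. On 3886 single-transcript genes limma-voom called 1177 and 834 genes where limma on FPKM called 1591 and 939. Of the lists, 17 were called with the preset correlation, and 17 to 18 without each neuroblast replicate in turn. With the estimated correlation, which has few residual degrees of freedom to estimate it, 0 were called. The estimates ran from -0.07 for photoreceptor markers to 0.90 for neurotransmitter genes, with 0.67 for DNA replication, against the preset 0.01. The p-values with the preset correlation thus take the members of a list as near independent, which these estimates mostly do not show. The correlation alone does not account for the 0 calls. Asymmetric division, with an estimate of -0.02, went from a camera adjusted p of 0.0103 to 0.431. The share of the authors' genes called in the same direction moved from 92.3% to 97.8% over genes past the filter in both tables, since genes not tested here then leave the denominator, and to 83.4% with own calls at an adjusted p under 0.01, a stricter threshold. The mean SD between biological replicates (0.698) was 1.05 with a pseudocount of 0.1, which widens low values. Reversed signs were Sr-CI (0.36) and Crz (0.17) with quantile normalization and Hsc70Cb (-0.0424) scaled to the sum of protein-coding FPKM. The cause was not tested for the first pair. Of 157 named genes, 18 lost their call without neuron replicate 1 and 26 without neuron replicate 2. Neuron 2 is the shallowest library, so low genes are least certain there.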

Other observations

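All tests of explanations in this part were chosen after the results were seen. Gene length in the files went with direction. With the tested genes in 4 equal classes of span, among the 1995 shortest (median 1058 bp) 1069 were higher in neuroblasts and 325 in neurons, with a median log2 fold change of 1.17. Among the 1994 longest (median 15811 bp) the counts were 243 and 1166 and the median was -1.17. The Spearman correlation of the log2 fold change with span was -0.45 across the 7975 genes, and with the longest transcript -0.43 across the 7560 with a transcript length, with genes not independent replicates. No explanation for this was tested. The gene lists were not set against genes of like span, so how far their medians go with span is not known. The spliceosome median of 0.96 lies below the 1.17 of the shortest class, and the DNA replication median of 3.91 above it.

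The 5 lists of neuronal genes stood at different levels in the neuroblast replicates. RNA from neurons in the neuroblast libraries would raise the lists by a like share, and the median excess over neuroblast 3 was 10.7% to 15.2% of the neuron level in neuroblast 1 and 4.87% to 6.84% in neuroblast 2, the highest list at most 1.43 times the lowest. For 90 genes with at least 50 FPKM in neurons and under 1% of that in neuroblast 3, the share in neuroblast 1 had a median of 10.5% and a range from the 10th to the 90th percentile of 6.94% to 17.5%. Neuroblast 1 also deviated from neuroblast 2 together with neuron 2, as given below (correlation 0.667). How far the excess in neuroblast 1 goes with that deviation was not tested. Depth is argued against: the technical replicates of neuroblast 3 differ 2.71 times in depth, and over 158 members their median shares differed by a factor of 1.04. Reads exchanged both ways on the shared flow cell are argued against too: they would bring neuroblast genes in neuron 1 to at least 4.87% of the neuroblast level, which the 35 DNA replication genes at 3.68% (bootstrap 95% interval of the median 2.51% to 6.78%) did not decide, but the 9 abundant neuroblast genes under 1% in neuron 2 stood at a median of 0.688%, 0.269% to 1.76% from the 10th to the 90th percentile (a minimum of 10 such genes, first asked for, was dropped after these values were seen), so that neurons in the sorted neuroblasts stay open.

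Heat shock and stress genes were higher in neurons in 18 of 25 cases. The list median was -1.74 as deposited, -1.87 with median ratio scaling, -1.98 with upper quartile scaling and -2.28 with the protein-coding sum. Quantile normalization gave -2.16. The median of all tested genes fell from 0.17 as deposited to 0.01, -0.17 and -0.53 with the first 3 alternatives. Those could thus not have raised the list, and they cannot decide whether the scaling has a part in its direction. The list median did lie below that of all tested genes with each of them. Reads shared between the 6 Hsp70 copies are argued against, since 14 of the 19 members outside them were higher in neurons. Handling that differed between the 2 sorted fractions cannot be told apart from cell type, because each cell type is one fraction: 20 of the 25 members stood higher in both neuron replicates than in every neuroblast replicate under either reading.

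Neuroblast 1 and neuron 2 deviated together from neuroblast 2 and neuron 1, with a correlation across 7975 genes of 0.667 between the 2 differences. Transcript length is argued against, since its Spearman correlation with the mean of the differences was 0.054. Genes that overlap a gene on the opposite strand differed from the rest by -0.012 in the median. Exchange with that strand could raise some genes and lower others, so this median cannot decide it. The 77 tested genes of chromosome 4 had a median of 1.04 against 0.08 on the other arms, above the highest of 10000 random sets matched on mean level (0.293). Base composition is a possible reading, since that chromosome is AT-rich, but composition itself was not measured. The random sets were matched on mean level only, so other traits of chromosome 4 were not separated from it. No biological explanation was tested, since no group of the design joins these 2 replicates.

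With limma, only the real one of the 10 splits of the 5 biological replicates into 3 and 2 gave as many genes, 1 split in all, with 5048 genes against at most 0 in the others (at most 1433 at an unadjusted p under 0.05). Every other split puts both cell types into at least 1 group, so that their difference adds to the spread within groups. The 0 calls of those splits were thus close to given in advance and do not bear on chance. With 10 splits no share under 0.05 can be had.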
